A study of Homo sapiens with 6 samples.

How the data were processed

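Per the labels, RNA was sequenced 36 hours after transfection from CFPAC-1 cells, a line derived from a metastasis of a human pancreatic ductal adenocarcinoma. The 6 libraries fall into 2 groups of 3 according to the labels. One group, named siUBE2C, received a small interfering RNA named for UBE2C, and the other, named siNC, is the control. Sequences and doses of the duplexes are not given in the sources used here. The labels describe the controls as matched but name no shared day or batch behind the replicate numbers, and nothing says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels' protocols record TRIzol extraction of total RNA and standard Illumina library preparation. Selection of poly(A) RNA, strandedness and read length are not given in the sources used here.

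The submitters' processing notes name HISAT2 2.0.4, Cufflinks 2.1.1 and Cuffdiff, with the genome build hg38/GRCh38, without the role or order of each tool. The counting tool, the annotation release and the use of strand are not given in the sources used here. The authors deposited, per the file headers, a table with a whole-number count and an FPKM value for each of 50868 genes in each of the 6 libraries, with gene symbols and coordinates. The deposited FPKM values equalled the count divided by a gene length and by the library's total count, with a largest relative deviation of 4.3e-06 over 8192 genes with at least 200 counts in every library, so they held no information beyond the counts and were not tested. Of the deposited genes, 25759 had a count of 0 in all 6 libraries, among them 4563 of 19691 protein-coding genes, so a level of 0 for a single gene was read only as listed at 0. Gene types, transcripts and exons were taken from GENCODE release 29 on GRCh38. In that release 50111 of the identifiers were found, and 94.9% of these had identical coordinates.

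Total counts ranged from 12906117 to 16258441 per library, and 19908 to 20793 genes had at least 1 count. Replicates were compared by a chi-square test over genes with at least 20 counts in the pair. The statistic per degree of freedom lay between 10.3 and 15.6 within groups and between 63.6 and 91.1 between groups, so no library was counted as a copy of another.

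Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group and its minimum count of 10, libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) compared siUBE2C with siNC, two-sided, with no covariate. Of all genes, 14524 were tested. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM with TMM-scaled totals, given as mean ± SD of 3 libraries. Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over the 24 lists, with camera at an estimated correlation and fry beside it. Fry, which tests a list by itself and not against the other genes, gave an adjusted p under 0.05 for 16 of the 24 lists, and camera for 8. For single values the exact two-sided permutation test was used, which with 3 against 3 cannot give a p under 0.1.

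Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names UBE2C; the 12 genes with the highest and the 12 with the lowest log2 fold change among genes past the threshold with a symbol, no pseudogene annotation, a mean of at least 5 CPM and no overlap between the groups' libraries; and up to 4 members of each list with the smallest adjusted p. Genes outside the rule are marked as chosen after their values were seen, and some genes named by the rule are not reported here. Alternatives were the replicate number as a block, DESeq2 1.42.0, edgeR with DESeq2 size factors, library totals without TMM, 2 other expression filters, limma-voom, each of the 6 libraries left out, an adjusted p of 0.01, a test against a fold of 1.2, an estimated correlation for the lists, and protein-coding genes only for the lists. A correction for GC content and length by natural splines with 5 degrees of freedom per library, over 14449 genes with both values, and thinning of every library to the smallest total were added after the data had been seen. The deposited table held no fold changes or p-values of the authors, so the planned comparison with such values was not analysed here.

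The edgeR steps were tested on simulated counts drawn from the means, totals and dispersions of these libraries for siUBE2C against siNC, with 14253 genes kept. Of these genes 14054 were left unchanged, whereas 7529 of 14524 genes were called in the data. The simulated shares therefore need not hold for the real comparison. Of 66 genes changed by a log2 fold of 0.5, 20 were recovered. Of 67 changed by 1 and of 66 changed by 2, 52 and 61 were recovered. Of the calls made, 11.9% were genes left unchanged, above the nominal share. A simulated shift of 0.5 in the proteasome list was called and none of the other 23 lists was. For the closing section, the log2 fold change of 12023 protein-coding genes was regressed on the presence of each of the 16384 words of 7 bases in the longest annotated 3' UTR, with UTR length and base composition as covariates, in Python 3.11.15 with numpy 2.4.6. With permuted fold changes, a word given an effect of -0.2 ranked first for 5 of 5 words.

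Reads of near-identical copies, such as ribosomal protein genes, keratins 8 and 18 and their pseudogenes, may have been split between rows, and levels of these genes are uncertain. The same holds for overlapping genes such as MT-ND4 and MT-ND4L, and for genes with an antisense partner.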

Results

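The data describe the transcriptome of cells labelled as CFPAC-1, a pancreatic cancer line, after transfection with a small interfering RNA named for UBE2C, the ubiquitin-conjugating enzyme that works with the anaphase-promoting complex in mitosis. The 3 siUBE2C libraries held 15214006, 16258441 and 12906117 counts and the 3 siNC control libraries 13897208, 14973407 and 14753023. The comparison asks which transcripts differ when the cells have received the duplex named for UBE2C in place of the control.

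UBE2C (ENSG00000175063, chromosome 20, 45812576 to 45816957, plus strand, GRCh38) was lower in every siUBE2C library than in any siNC library. Its counts were 1428, 1530 and 1548 in siNC and 452, 668 and 474 in siUBE2C. The normalized level was 110 ± 2.98 CPM in siNC and 33.8 ± 5.41 CPM in siUBE2C (SD, n = 3 each), which leaves 30.8% of the control level. The log2 fold change was -1.70 (SE 0.11, adjusted p = 9.94e-06, edgeR quasi-likelihood test). The exact permutation test of these values gave p = 0.1, the smallest that 3 against 3 allows. By size of decrease UBE2C ranked 214 among the 14524 genes tested.

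**Figure D1:**
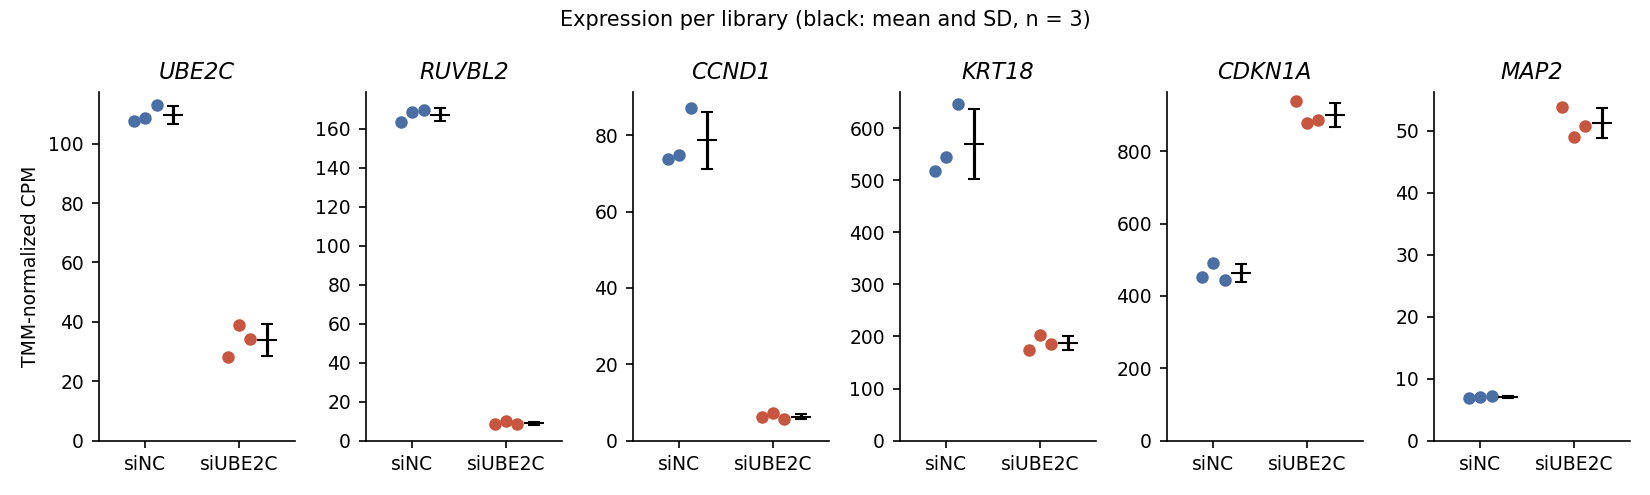
Normalized level (TMM-normalized CPM, each axis from 0) of 6 named genes, with a point per library, siNC in blue and siUBE2C in red, and the mean and SD of 3 libraries in black. UBE2C fell from 110 to 33.8 CPM and RUVBL2 from 167 to 9.01 CPM, while CDKN1A rose from 462 to 901 CPM.

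The change reached far beyond UBE2C. The gene with the smallest p and the largest decrease under the naming rule was RUVBL2 (ENSG00000183207, chromosome 19, 48993448 to 49015995, plus strand), which encodes an AAA ATPase of chromatin remodelling complexes. It fell 18.5-fold, from 167 ± 3.48 to 9.01 ± 0.797 CPM (log2 fold change -4.21, SE 0.08, adjusted p = 9.82e-08). CCND1, which encodes cyclin D1, fell 12.4-fold from 78.6 ± 7.47 to 6.32 ± 0.725 CPM (chromosome 11, 69641087 to 69654474). The long noncoding RNA UCA1 fell 9.07-fold from 368 ± 67.3 to 40.6 ± 7.52 CPM, and SZRD1 8.87-fold from 180 ± 12.1 to 20.3 ± 4.14 CPM. The focal adhesion gene TNS4, the endothelin gene EDN2, ANKRD2, NCCRP1, AMMECR1, the phosphatase gene DUSP9, the translation repressor gene EIF4EBP1 and the histone gene H2AFX completed the 12 strongest decreases under the naming rule. Their log2 fold changes ran from -3.58 for TNS4 to -2.76 for H2AFX. Relative to its mean level EDN2 varied most of these 12, at 18.3 ± 11.5 CPM in siNC and 1.8 ± 0.798 CPM in siUBE2C. Without siNC replicate 3 the log2 fold change of EDN2 was -2.69.

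Among genes that rose, GUCY1A2 (chromosome 11, 106674012 to 107018524, minus strand), a subunit gene of soluble guanylate cyclase, went from 3.34 ± 1.56 to 35 ± 2.66 CPM, a 10.4-fold increase (log2 fold change 3.38, SE 0.28, adjusted p = 1.08e-04). The vesicle membrane gene SCAMP5 rose 9.81-fold to 9.66 ± 1.09 CPM. MAP2, which encodes a microtubule-associated protein of neurons, rose 7.30-fold from 7.01 ± 0.154 to 51.3 ± 2.47 CPM, and the cardiac actin gene ACTC1 5.61-fold from 14.4 ± 4.27 to 80.5 ± 1.44 CPM. DYNC1I1, PRKCB, APH1B, the sodium leak channel gene NALCN, ICA1L, the ciliary transcription factor gene RFX3, HHAT and the kainate receptor gene GRIK2 completed the 12 strongest increases under the naming rule. Their log2 fold changes ran from 2.45 for DYNC1I1 to 2.17 for GRIK2.

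Of the 14524 genes, 3710 were higher and 3819 lower in siUBE2C at an adjusted p under 0.05, and 930 and 944 of these changed at least 2-fold. The groups did not overlap in 61.7% of the genes tested, against 10% by chance. With library totals in place of TMM, which moved the median log2 fold change of all genes to 0.18, 5244 were higher and 2750 lower, so 65.6% of the calls were increases in place of 49.3%. Below, changes are relative to the TMM-scaled libraries, in which the median over all genes was 0.01.

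**Figure D2:**
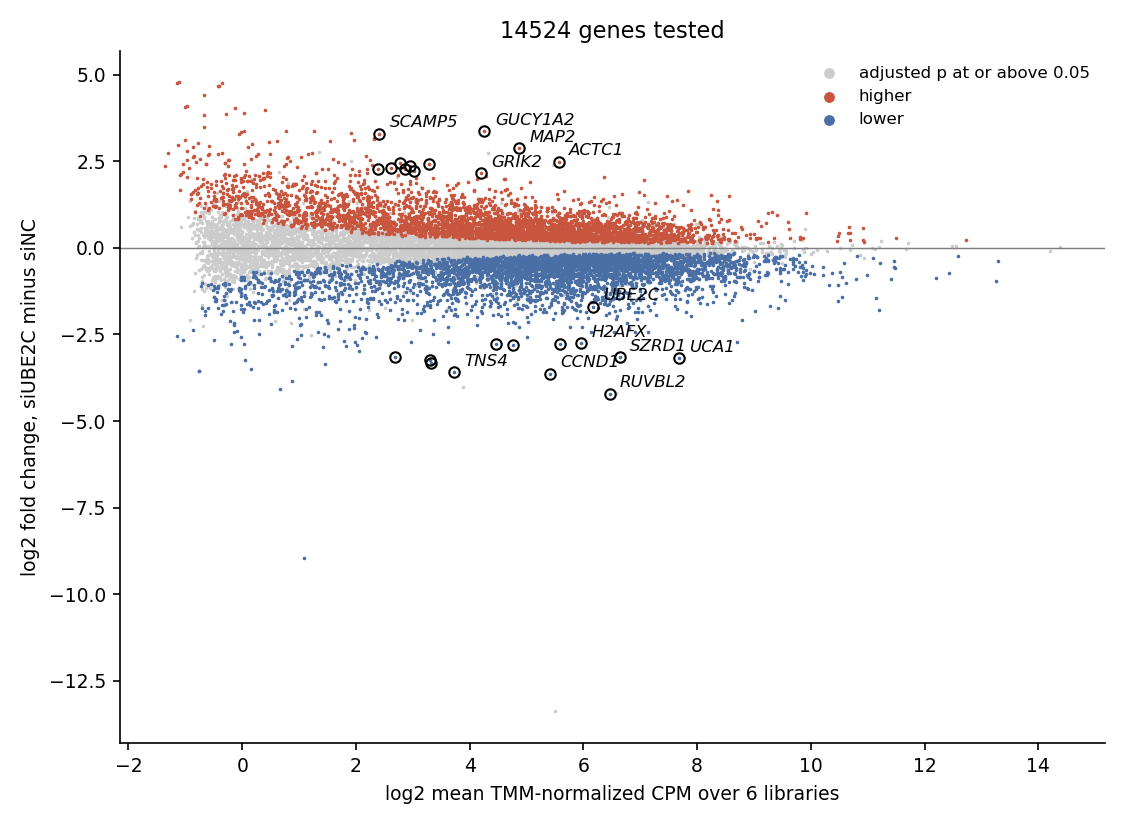
Log2 fold change (siUBE2C minus siNC) against the log2 mean level over the 6 libraries for the 14524 genes tested, with 3710 higher genes in red, 3819 lower genes in blue and the rest in grey. Circles mark UBE2C and the 12 highest and 12 lowest genes of the naming rule, of which RUVBL2 at -4.21 lies lowest.

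Genes of cell division fell together. Where no member of a list rose, or none fell, the count was 0 also at an unadjusted p under 0.05 and with DESeq2 or limma-voom. In the list of 60 mitosis and G2/M genes, 59 fell and none rose, both over all genes and adjusted over the list alone, with a median log2 fold change of -1.47. The cytokinesis genes ECT2, CEP55 and KIF23 fell 2.59-fold, 3.92-fold and 2.75-fold, and the spindle gene SPAG5 3.43-fold from 309 ± 7.6 to 90.3 ± 8.97 CPM. The proliferation marker MKI67, named after its values were seen, was the member without a call, at 374 ± 198 CPM in siNC and 210 ± 28.3 CPM in siUBE2C. UBE2C itself, which is in no list, fell more than 52 of these 60 genes. In the list of 60 S phase and DNA replication genes, 57 fell and none rose, again also adjusted over the list alone, with a median of -0.98. Besides CCND1, the transcription factor gene E2F2 fell 4.53-fold, the thymidine kinase gene TK1 3.36-fold from 170 ± 11.1 to 50.5 ± 3.47 CPM, and the thymidylate synthase gene TYMS 2.29-fold. Camera gave adjusted p = 7.43e-65 for mitosis and 1.19e-33 for S phase at the preset correlation, and adjusted p = 0.216 with an estimated correlation for each.

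The anaphase-promoting complex and its partners, among which UBE2C acts, were not called as a set by camera after the edgeR fit (adjusted p = 0.0991), but were after DESeq2 (0.0192), with every gene with a count (0.0464) and by fry (adjusted p = 0.000612). Of 22 members 10 fell and 4 rose, also adjusted over the list alone. The members that fell most were regulators and partners of the complex. CDC20 fell 3.44-fold, the inhibitor gene FBXO5 2.86-fold, the checkpoint gene MAD2L1 2.58-fold, and UBE2S, the E2 that extends the ubiquitin chains that UBE2C starts, 2.32-fold. Among 35 tested E2 genes other than UBE2C, 11 fell and 7 rose, led by UBE2T, UBE2S, UBE2Z and UBE2L3 with folds of 2.15, 2.32, 2.09 and 1.48, all lower (camera adjusted p = 0.535). Proteasome subunit genes rose in 14 of 35 cases, 11 adjusted over the list alone, and none fell. PSMD10, PSMC2, PSMD6 and PSMC1 rose by log2 folds of 0.50, 0.30, 0.44 and 0.34. The set missed the threshold (camera adjusted p = 0.0901). It passed in 5 of 11 other settings with all 6 libraries, among them DESeq2 (0.0102), library totals (0.0184) and limma-voom (0.0061). With a library left out it passed in 2 of 6 fits, without siNC replicate 3 (0.0339) or siUBE2C replicate 2 (0.0454).

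Targets of the tumour suppressor p53 rose on balance. Of 36 tested, 20 rose and 6 fell, also adjusted over the list alone, with a median log2 fold change of 0.29. CDKN1A, the gene of the cell cycle inhibitor p21, rose 1.95-fold from 462 ± 24.7 to 901 ± 33.1 CPM. The proapoptotic gene BBC3 rose 2.75-fold from 5.27 ± 0.377 to 14.5 ± 0.326 CPM, TP53I3 2.09-fold, and MDM2, the gene of the ubiquitin ligase of p53, 1.91-fold. Camera gave adjusted p = 0.00135, and adjusted p = 0.216 with an estimated correlation. Apoptosis regulators split, with 8 higher and 8 lower of 33 tested (8 and 7 adjusted over the list alone, camera adjusted p = 0.804). BBC3 and BAK1 rose, the latter 1.61-fold, whereas the inhibitor gene BIRC3 fell 1.59-fold. The median and mean of that list, -0.02 and -0.08, lay below 0 while camera's direction was upward.

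Epithelial markers fell. Of 40 listed, 27 were tested, 20 fell and none rose, also adjusted over the list alone, with a median of -0.63 (camera adjusted p = 1.39e-08, adjusted p = 0.216 with an estimated correlation). The membrane traffic gene MAL2 fell 4.92-fold from 48.4 ± 5.26 to 9.82 ± 0.824 CPM, the epithelial transcription factor gene ELF3 3.08-fold, the keratin gene KRT18 3.03-fold from 570 ± 67.4 to 188 ± 13.7 CPM, and the tight junction gene TJP1 2.07-fold. Mesenchymal markers moved both ways, with 7 higher and 14 lower of 31 tested (8 and 15 adjusted over the list alone, median -0.10, which turned to 0.07 with library totals, camera adjusted p = 0.605). The smooth muscle actin gene ACTA2 rose 3.15-fold, WNT5A 2.12-fold from 153 ± 9.64 to 324 ± 21.5 CPM and the integrin gene ITGAV 1.59-fold. Of 23 tested TGF-beta targets 6 rose and 9 fell, the same adjusted over the list alone (camera adjusted p = 0.605). ID3 rose 1.64-fold, and BHLHE40 and TGFB1 fell 2.64-fold and 1.75-fold.

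Most duct, squamous, blood and acinar markers were under 1 CPM in both groups. Of 17 fibroblast and stellate cell markers, 7 were under 1 CPM in siNC and 8 in siUBE2C. Only 9 of 35 pancreatic duct and gastric mucin markers passed the expression filter, and SMAD4, a gene reported as deleted in CFPAC-1 and chosen after its values were seen, stood at 75.2 ± 3.99 CPM in siNC and 59.8 ± 4.11 CPM in siUBE2C. Of these, the keratin gene KRT7 fell 2.01-fold from 2113 ± 293 CPM, the carbonic anhydrase gene CA9 2.52-fold and the transcription factor gene GATA6 1.49-fold, and 1 member rose (same counts adjusted over the list alone, camera adjusted p = 0.0829). That list passed the threshold without siNC replicate 1 (adjusted p = 0.0479), without siNC replicate 2 (0.0266) without siUBE2C replicate 1 (0.0391) and after thinning to the smallest total (0.0451). Among squamous and basal markers 7 of 30 were tested, 1 rose and 3 fell (4 adjusted over the list alone), with TRIM29 down 1.88-fold from 340 ± 18.7 CPM and KRT17 down 2.66-fold. Among fibroblast and stellate cell markers 10 of 17 were tested, 3 rose and 3 fell in either adjustment, with FBN1 up 1.67-fold from 578 ± 33.6 CPM and COL5A1 down 1.63-fold from 672 ± 97.2 CPM. Of 26 blood and endothelial markers 3 were tested, and CDH5 and TEK fell from 3.01 ± 0.83 and 1.1 ± 0.298 CPM to 0.169 ± 0.022 and 0.079 ± 0.089 CPM. Of 27 acinar and islet markers 2 were tested, and AMY2B rose from 0.511 ± 0.066 to 1.51 ± 0.358 CPM while PCSK1 fell from 1.34 ± 0.251 to 0.598 ± 0.085 CPM, a call lost with DESeq2 (adjusted p = 0.0813). For the blood and acinar lists counts were the same adjusted over the list alone. Camera gave adjusted p = 0.271 for squamous, 0.847 for fibroblast, 0.0991 for blood and 0.847 for acinar markers.

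Interferon response genes rose. Of 38 tested, 27 rose and 3 fell, also adjusted over the list alone, with a median log2 fold change of 0.69 (camera adjusted p = 7.13e-05, adjusted p = 0.297 with an estimated correlation). The double-stranded RNA sensor gene IFIH1 rose 2.76-fold from 7.95 ± 1.25 to 22 ± 1.01 CPM, DDX60 1.99-fold and SAMD9 1.63-fold. OAS3, of the family that activates RNase L, went the other way and fell 2.43-fold from 77 ± 2.16 to 31.7 ± 0.91 CPM. In the small RNA pathway and transfection response list, 2 rose and 7 fell of 16, also adjusted over the list alone, and the set was not called (camera adjusted p = 0.287). The Argonaute gene AGO2 fell 1.54-fold and the microRNA processing gene DGCR8 1.69-fold.

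Hypoxia and glycolysis genes fell in 30 of 34 cases and none rose, also adjusted over the list alone, with a median of -0.88 (camera adjusted p = 2e-10, adjusted p = 0.371 with an estimated correlation). PDK1 fell 2.31-fold, CA9 2.52-fold, ANKRD37 2.66-fold and the glucose transporter gene SLC2A1 2.83-fold from 169 ± 30.7 to 59.5 ± 6.51 CPM. Immediate early and ERK output genes fell in 20 of 33 cases and 1 rose over all genes, 3 adjusted over the list alone, with a median of -0.84 (camera adjusted p = 4.73e-05, adjusted p = 0.297 with an estimated correlation). Besides CCND1, the feedback inhibitor gene SPRY1 fell 7.81-fold and the ETS factor gene ETV4 5.06-fold, whereas the phosphatase gene DUSP2 rose 2.61-fold from 31.2 ± 2.47 to 81.5 ± 2.36 CPM. Of 16 tested NF-kB and cytokine genes 8 fell and 1 rose, 2 adjusted over the list alone (camera adjusted p = 0.271), with TNFAIP2, BIRC3 and CCL2 lower and RELB higher. Of 36 unfolded protein and integrated stress response genes 13 rose and 8 fell, 9 adjusted over the list alone (camera adjusted p = 0.459). The cystine transporter gene SLC7A11 rose 2.82-fold from 197 ± 24.9 to 555 ± 31.6 CPM and DNAJC3 1.53-fold, whereas MTHFD2 fell 2.71-fold and DDIT4 2.35-fold. Of 33 cholesterol and fatty acid synthesis genes 8 rose and 2 fell, also adjusted over the list alone. TM7SF2, MVD and INSIG1 rose, with log2 fold changes of 1.61, 0.92 and 0.52. The set missed the threshold (camera adjusted p = 0.0592). It passed in 6 of 11 other settings with all 6 libraries, among them the replicate block (0.0368), DESeq2 (0.0099) and limma-voom (0.0479). With a library left out it passed in 3 of 6 fits, without siNC replicate 1 (0.00621), siNC replicate 2 (0.0188) or siUBE2C replicate 2 (0.05 after rounding).

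Transcripts of cytosolic ribosomal proteins fell in 72 of 78 cases and none rose, 74 adjusted over the list alone, with a median of -0.66 (camera adjusted p = 1.01e-20, adjusted p = 0.216 with an estimated correlation). RPL5 fell 2.51-fold from 517 ± 26.8 to 206 ± 15.2 CPM, RPL30 2.59-fold, RPL37 1.80-fold and RPS12 1.82-fold. These genes took 2.77 ± 0.115% of all counts in siNC and 1.94 ± 0.0166% in siUBE2C, and processed pseudogenes 3.06 ± 0.0764% and 2.22 ± 0.0217%. Mitochondrial genes took 7.93 ± 0.267% and 8.72 ± 0.442% (exact permutation p = 0.1 for each of the 3 shares, the smallest possible). Of 13 mitochondrially encoded mRNAs 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.68), with MT-CYB up 1.22-fold and MT-ND4 down 1.31-fold. The call of MT-ND4 was lost with library totals (adjusted p = 0.0567). The 10 most abundant genes took 9.66 ± 0.188% of counts in siNC and 9.31 ± 0.371% in siUBE2C (exact permutation p = 0.2).

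**Figure D3:**
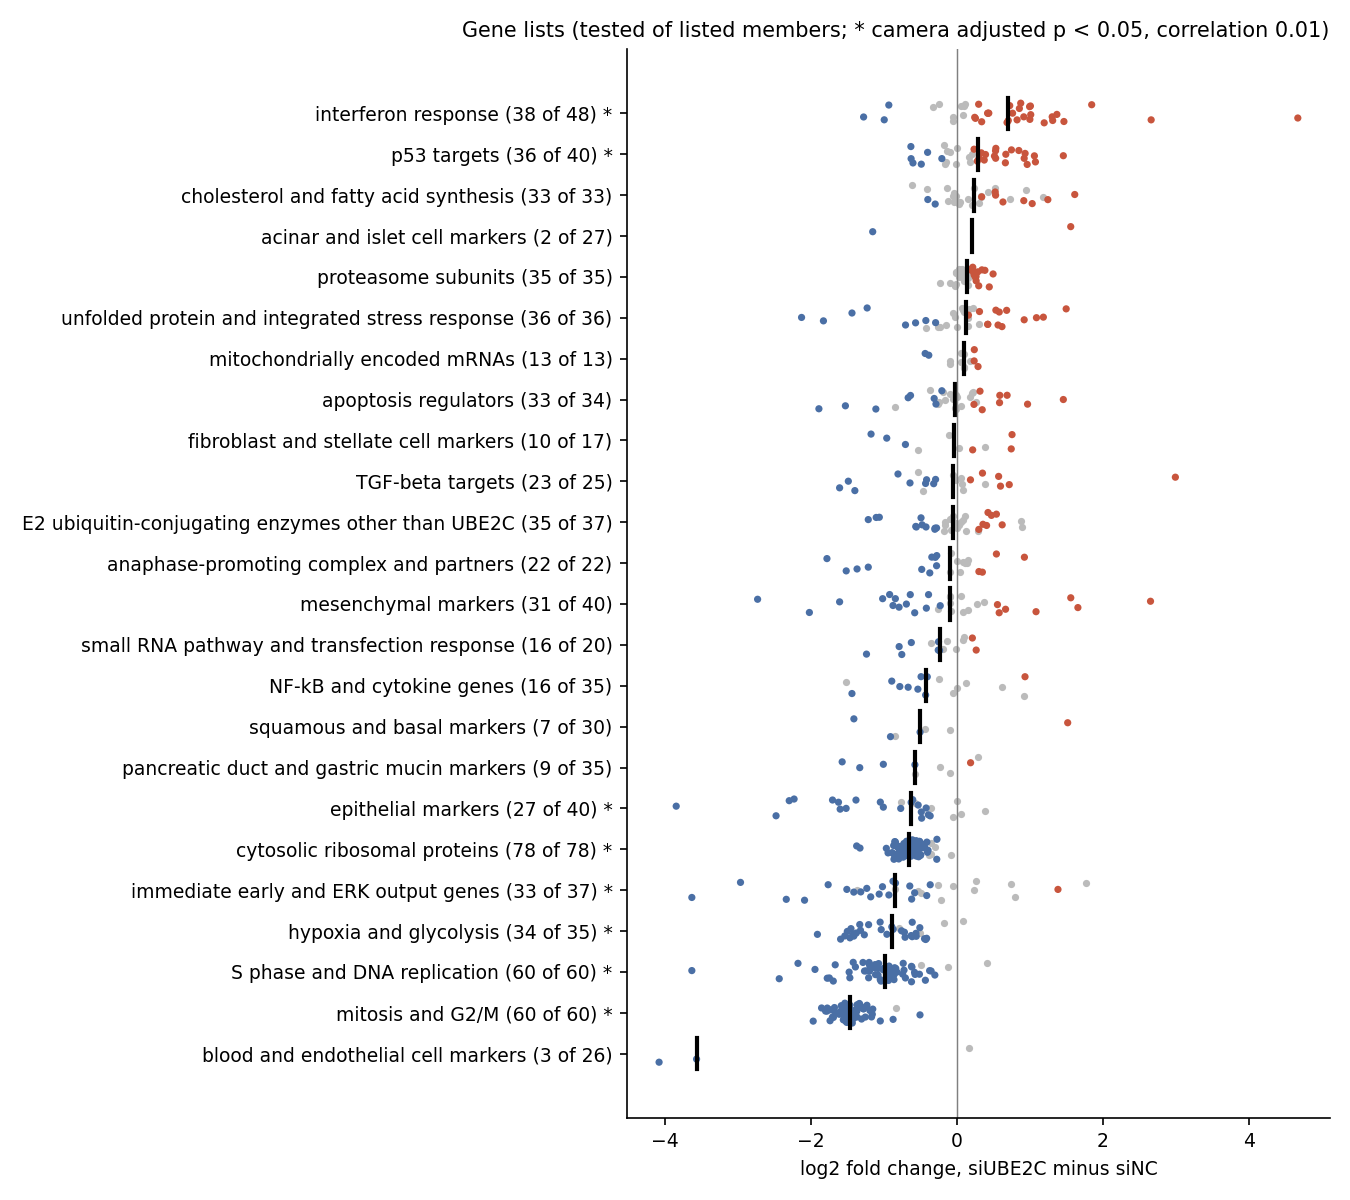
Log2 fold change (siUBE2C minus siNC) of every tested member of the 24 gene lists, a point per gene, red where higher and blue where lower past adjusted p 0.05 and grey otherwise, with the list median as a black bar. The medians of the mitosis list at -1.47 and of the ribosomal protein list at -0.66 lie below 0 and that of the interferon list at 0.69 above it, and the medians of the mesenchymal, anaphase-promoting complex, other E2, TGF-beta, apoptosis and fibroblast lists, all between -0.10 and 0, turn positive with library totals.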

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

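The correction for GC content and length and the thinning were chosen after seeing the data; the other alternatives were planned. UBE2C stayed lower and past the threshold in all 15, with log2 fold changes from -1.81 to -1.53. The counts of genes past adjusted p 0.05 stayed within 1.5 times, from 5349 (adjusted p 0.01) to 7994 (library totals), and from 6494 to 6959 with a library left out. The count with a fold of 2 moved to 1055, 420 of them higher, for genes of mean CPM at least 5, which tests fewer genes, and was 1742 to 1939 with a library left out. The replicate block gave 7023 calls, 6820 of them shared with the unblocked fit in the same direction. In their departures from the group mean, same-numbered samples correlated at -0.03, -0.14 and -0.05, and no sample correlated best with its own number. No variation shared by number was seen, which cannot tell whether the samples were prepared in pairs. With an estimated correlation no list was called (smallest adjusted p = 0.216; 5 were under 0.05 unadjusted): the medians, -1.47 (mitosis), -0.98 (S phase), 0.29 (p53) and -0.63 (epithelial), are unaffected by that choice. Lists without a call changed camera's direction 4 times, and the cause was not tested: fibroblast markers with DESeq2 (median 0.12), blood markers at mean CPM at least 5 (0.19), and apoptosis regulators with limma-voom (-0.053) and without siNC replicate 3 (-0.080; -0.081 to -0.0043 over the libraries left out). No acinar marker was left at mean CPM at least 5. No named gene reversed. In the simulation, where most genes were left unchanged, 20 of 66 changes of 0.5 on the log2 scale were recovered. The real comparison called smaller changes too, such as PSMC2 at 0.30 (adjusted p = 0.00179, edgeR quasi-likelihood test). That share therefore need not hold here, though small changes may still be missed.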

Other observations

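The tests of other splits, library size, GC content with length and UBE2C words were set before their results were seen; the other tests here, and every gene here outside the rule for named genes, were chosen after. EGFR, which encodes the epidermal growth factor receptor, fell 3.47-fold from 3649 ± 328 to 1051 ± 102 CPM (SD, n = 3; log2 fold change -1.80, SE 0.09). The vimentin gene VIM fell 6.64-fold from 724 ± 47.1 to 109 ± 28.8 CPM. The urea cycle gene CPS1 fell 1.19-fold from 6673 ± 394 CPM, and the placental alkaline phosphatase gene ALPP fell from 3447 ± 374 to 2291 ± 106 CPM. The long noncoding RNA LINC01021 rose 2.51-fold from 49.9 ± 6.61 to 125 ± 1.72 CPM. All 5 passed an adjusted p of 0.05 in the edgeR test.

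The first pattern is the breadth of the change, with 7529 of 14524 genes called. Correcting for GC content and length left 7578 calls, which argues against these biases as the whole source. Thinning all libraries to the smallest total left 7316 calls. Mean totals were already close, at 14792855 counts in siUBE2C and 14541213 in siNC (exact permutation p = 0.8). The edgeR test also scales each library, so little change after thinning was set in advance and the thinning decides nothing about depth. Of the 10 splits of the libraries into 3 and 3, only the real one (1) gave as many calls. The highest other split gave 0 with edgeR or limma-voom (163 at an unadjusted p under 0.05, and 11 with DESeq2). Every other split holds siNC and siUBE2C libraries on both sides, so the group difference widens the spread within each side. Few calls were thus set in advance, and 10 splits are too few for a share under 0.05, so the test decides nothing. Loss of UBE2C and any other effect of the same duplex cannot be told apart, since the labels describe only 1 treated group.

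The second pattern is a sequence that was more frequent in genes that fell. Across 12023 genes, the 3' UTR word ACCAGCA went with the lowest fold changes (t = -13.45, against a lowest t of -4.48 in 20 shufflings). Its estimated effect was -0.26 on the log2 scale. Of genes with ACCAGCAA, 44.3% were called lower and 16.1% higher, against 24.6% and 28.3% without the 6 bases CCAGCA. Many lower genes lacked the word, as 1563 held no match, against 187 with ACCAGCAA and 469 with ACCAGCA alone. The median log2 fold change was -0.25 in 422 genes with ACCAGCAA, -0.12 in 1278 with ACCAGCA alone and -0.05 in 933 with CCAGCAA alone. It was 0.02 in 3033 with the 6 bases CCAGCA and 0.04 in 6357 without them. This order may reflect silencing by a small RNA in the siUBE2C cells whose seed pairs with that word, as a hypothesis. The planned test gave 4 UBE2C words among the lowest 20, where 7.41% of all words are UBE2C words (binomial p = 0.0561), but many of the 20 overlap one another and are not independent draws, so it decides nothing; the leading word or its reverse complement occurs in 0 of 8 annotated UBE2C transcripts, which argues against the seed of a duplex fully matched to UBE2C. RUVBL2, ranked 1 of all genes by p, carries ACCAGCAA in the coding sequence. The site lies in exon 6 of 15 of an annotated coding transcript (chromosome 19, 49007353 to 49007360, plus strand, GRCh38). Pairing of such a small RNA with RUVBL2 is thus a candidate explanation for its 18.5-fold fall. However, 9.9% of the mRNAs carry the site. The 781 others with it only outside the 3' UTR had a median log2 fold change of -0.09. The lowest of them, at -3.15, also fell strongly, but less than RUVBL2. Without the duplex sequences this explanation stays open. The fall of UBE2C by 1.70 on the log2 scale lies within the range of the mitosis genes, so a direct and an indirect fall of UBE2C stay open too.

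The third pattern is the low level of duct markers in cells described as CFPAC-1. In siNC 27 of 35 duct markers were under 1 CPM, so loss in siUBE2C is not the source. Of these 27, 17 had at least 1 count in any library, so most rows were not wholly empty. A row that lost nearly all its reads in the counting could still hold a count, so loss in the counting stays open. CFTR stood at 0.143 ± 0.187, KRT19 at 0.248 ± 0.245, EPCAM at 0.024 ± 0.041 and CDH1 at 0.556 ± 0.259 CPM in siNC, while KRT7 reached 2113 ± 293 and KRT18 570 ± 67.4 CPM. Of 40 epithelial markers 14 were under 1 CPM in siNC (median 4.94 CPM, against 0.074 CPM for duct markers). Besides EPCAM and CDH1 these included ESRP1 at 0.097 ± 0.042 and GRHL2 at 0.024 ± 0.041 CPM. Of 40 mesenchymal markers 31 passed the expression filter, against 27 of 40 epithelial markers. Among the former, VIM stood at 724 ± 47.1 and CDH2 at 59.2 ± 3.46 CPM in siNC. SMAD4, which CFPAC-1 is reported to have lost by homozygous deletion, was at no less than 57.0 CPM in any library, which is consistent with cells of another line, as a hypothesis. A genotype of the cells was not analysed here, and no comparison with expression profiles of named lines was made.

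The highest t of any word was 5.32, for GTAGCGC in 116 genes, against 4.84 in the shufflings. The pseudogene EEF1A1P5 took 0.649 ± 0.0154% of counts in siNC and 0.442 ± 0.0083% in siUBE2C. Single libraries departed from both others of their group by more than 1.5 on the log2 scale, with those others within 0.5, in 9 to 18 of 9990 genes with a mean of at least 10 CPM.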
